A study of Mus musculus with 12 samples.

How the data were processed

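RNA from mouse CD4+ T cells was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, with 2 arrays for each of 6 groups (12 arrays). The deposited values are probe set signals, intensities on a linear scale, computed with MAS5 per the submitters' processing notes and with GCOS 1.1.1 per the labels, which also name GeneSpring GX 7.3.1 for the submitters' own analysis. MAS5 sets a perfect-match probe against its mismatch partner and scales each array to a target mean. Per the deposited intensities themselves, the 2% trimmed mean of each array (2% of values left out at each end) was 1000 for Th1, Th2 and Th17 and 500 for naive, iTreg and nTreg. All values were above 0. Every column of per-sample values was used. The number of arrays limits the precision, and the labels give no scan date.

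The design fixed before the data were examined took the signals as scaled alike on all arrays. As they were not, every array was first rescaled to a trimmed mean of 500, and the deposited scaling was kept as an alternative. That scaling sets the Th1, Th2 and Th17 arrays 2-fold apart from the others by construction, which moves the share of higher calls in comparisons across them. Values were then taken as log2(signal + 23), where 23 is the 25th percentile of the deposited values, so fold changes are on that scale and understate the change of dim genes. Probe sets were named through a table of the platform annotation. Of 45101 probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here. Entrez identifiers of 34741 matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Probe sets with several symbols or none were left out of gene tests. Each of 18193 genes was represented by its probe set with the highest mean log2 value over the 12 arrays, and 9010 genes had more than 1 probe set. Genes at or above an array's median probe set in at least 2 of the 12 arrays were tested, which left 12366.

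Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend, two-sided), with 1 term per group over all 12 arrays, 6 residual degrees of freedom and a prior of 7.56. Benjamini-Hochberg adjustment ran over the genes of each comparison at 0.05. There were 8 comparisons, with groups weighted equally: the cultured subsets against naive cells, each of Th1, Th2, Th17 and iTreg against the mean of the other cultured subsets, nTreg against naive, iTreg against nTreg, and the difference between the nTreg and iTreg changes. Of 10 lineage genes, 9 had a named probe set, and these were tested in each group against naive cells with adjustment over that family. Standard errors are limma's moderated ones.

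Gene lists were written beforehand, 20 in all: Th1, Th2, Th17, Treg and Tfh programmes, naive and quiescence, cell cycle, glycolysis, cholesterol synthesis, TGF-beta response, interferon response, immediate early genes, chromatin modifiers, chemokine receptors, B cell, myeloid and dendritic, CD8 and NK and erythroid markers, sex-linked genes and lineage factors. The last 2 were described by value, and the erythroid list had fewer than 4 tested genes, so 17 lists were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, and with fry. Camera compares a list with the other genes and fry tests it against no change, so ranges over alternatives with camera leave fry out. The lists described for each comparison were chosen after their results were seen, and the number of lists past the test is given with each. The rule for named genes took, per comparison, the 8 largest rises and 8 largest falls among genes past the test whose arrays did not overlap between sides, without clone, predicted-gene and accession-like names or antigen receptor segments. It also took the 4 members with the largest change of each described list, all Treg programme members in the last comparison, and the lineage genes. Genes named in the account of array sets or of other cells outside that rule (Kdm5d, Uty, Car1 and the genes of the closing tests) were chosen after their values were seen.

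On simulated values with the real means and spreads of the 12366 genes, 200 genes were changed. For Th1 against the other cultured subsets 52.2%, 77.6% and 93.9% of genes changed by 1.5-fold, 2-fold and 4-fold were found, with 3.87% false calls. For nTreg against naive cells the shares were 43.3%, 58.2% and 90.9%, with 6.57% false calls, and for iTreg against nTreg 43.3%, 67.2% and 89.4%, with 4.32%. Camera found 1 shifted list of 20 genes in the Th1 comparison and called 0 of 50 unshifted lists. Genes were drawn independently, so the simulation cannot test the preset correlation. In the data that setting matters: the cell cycle list in cultured against naive cells had camera adjusted p = 8.0e-19, and 0.0266 with an estimated correlation. The simulation also changed a far smaller share of genes than was called in the data.

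The alternatives were quantile normalization, scaling to one median, a pseudocount 10 times smaller or 4 times larger, no filter and a filter at the 75th percentile, the mean of a gene's probe sets, the replicate number as a block, no variance trend, only the arrays of a comparison, and leaving out each array in turn. After the arrays were seen to form 2 sets, the deposited scaling and comparisons within a set were added, and the difference of Tbx21 between iTreg and Th1 was then run under the alternatives too.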

Results

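Gene expression was measured in mouse CD4+ T cells of 6 kinds, with 2 arrays for each. Naive cells and natural regulatory T cells (nTreg, sorted as CD25hi CD4+ cells) had been isolated and not cultured. Th1, Th2, Th17 and induced regulatory T (iTreg) cells had been cultured for 10 days under conditions that favour each subset. The title and design text name the profiling of T helper subsets and the plasticity of T cells, so the comparisons ask which transcripts set each subset apart. Each array gave 1 signal for each of 45101 probe sets, and 12366 genes were tested. The number of arrays limits the precision. Replicate arrays correlated across genes with r between 0.977 in naive cells and 0.989 in iTreg, and 94.2% to 97.3% of genes lay within 2-fold between replicates. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

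The arrays fell into 2 sets of 6 that did not mix groups. The Th1, Th2 and Th17 arrays had been scaled to a trimmed mean of 1000 and the naive, iTreg and nTreg arrays to 500. Poly-A spike controls, added before labelling, had geometric mean signals of 285 to 713 on the first set and 6.14 to 11.5 on the second. Xist, the RNA of the inactive X chromosome of female cells, had log2 signals of 14.1 to 14.3 on the first set and 5.13 to 7.18 on the second. The Y-linked gene Eif2s3y had log2 signals of 5.0 to 5.76 on the first set and 10.7 to 11.7 on the second, and Kdm5d and Uty, also Y-linked, were likewise higher on the second. The ratio of 3' to 5' signal for the transferrin receptor control was 2.02 to 2.67 on the first set and 4.28 to 19.6 on the second, with the highest value on naive replicate 1. Hybridisation controls had geometric means of 20628 and 21687 on the naive arrays and at most 8002 on every other array. Comparisons between iTreg and the other cultured subsets, and of Th1, Th2 and Th17 with naive cells, therefore also compare the 2 array sets and the sex of the donors, and values within a set are given where it holds more than 1 side of a comparison. The naive arrays also had maximum signals of 130747 and 140359, against at most 54193 on the iTreg and nTreg arrays. Values of iTreg or nTreg against naive cells within the set may therefore still carry a difference between arrays.

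**Figure D1:**
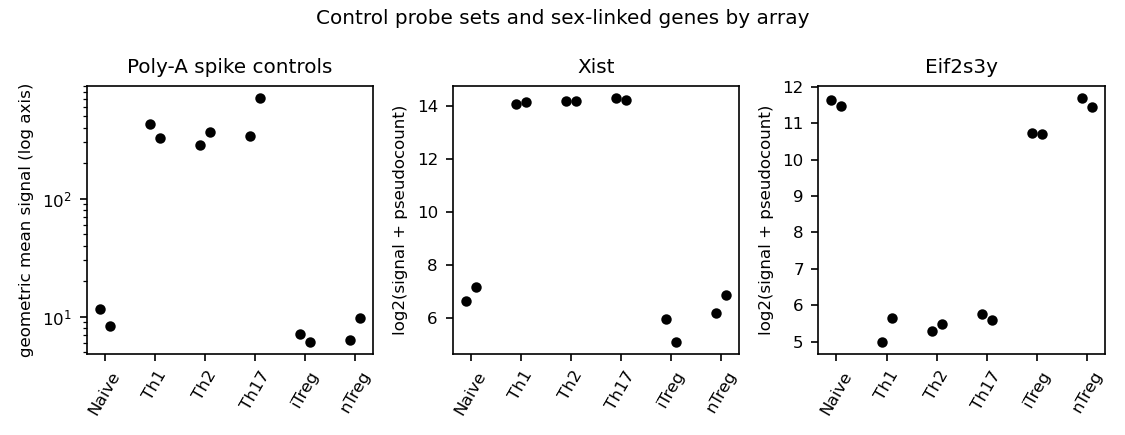
Poly-A spike control signal (geometric mean over 12 probe sets, log axis), and log2 signals of Xist and Eif2s3y, for each of the 12 arrays by group, with 1 point per array. Th1, Th2 and Th17 arrays carry spike signals of 285 to 713 and Xist of 14.1 to 14.3, and the other 6 arrays carry spike signals of 6.14 to 11.5 and Xist of 5.13 to 7.18.

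The genes that define the lineages differed between the groups. In Th1 cells Tbx21, the T-bet transcription factor, was 4.12-fold above naive cells (log2 2.04 ± 0.20 SE, 2 arrays each) and Ifng, encoding interferon gamma, was 4.79-fold above. In Th2 cells Gata3, the Th2 transcription factor, was 12.1-fold above naive cells (log2 3.60 ± 0.12 SE), Il4 was 19.5-fold and Il10 was 152-fold above. In Th17 cells Il17a was 106-fold (log2 6.72 ± 0.27 SE) and Il21 169-fold above naive cells, and Ifng was 2.60-fold above. Foxp3, the transcription factor of regulatory T cells, was 14.2-fold above naive cells in iTreg (log2 3.83 ± 0.28 SE) and 21.7-fold in nTreg (log2 4.44 ± 0.28 SE). Tbx21 was also 3.98-fold above naive cells in iTreg, where its log2 level of 9.80 ± 0.02 (SD, n = 2) differed from the 9.84 ± 0.08 (SD, n = 2) of Th1 by -0.05 ± 0.20 (SE, adjusted p = 0.858). The 2 groups lie on different array sets. With the deposited scaling the difference was -1.03 (adjusted p = 0.000583), but that scaling sets the array sets 2-fold apart by construction. Over the others of 23 alternatives it was -0.11 to 0.27. In nTreg, Gata3 was 2.92-fold, Il10 6.47-fold and Ifng 2.38-fold above naive cells. Bcl6, the transcription factor of follicular helper cells, was 5.78-fold lower than naive in Th1, 9.01-fold lower in Th2 and 2.29-fold lower in iTreg. Its Th17 level differed from naive by -0.05 ± 0.19 (SE, adjusted p = 0.868).

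Of 45 tests on 9 of these genes, 30 passed at an adjusted p of 0.05 over the family (limma, Benjamini-Hochberg), 17 higher and 13 lower than naive, or 56.7% higher against 74.1% with the deposited scaling. The 27 tests of Th1, Th2 and Th17, 21 of them past the test, cross the array sets, so their folds carry array set and donor sex too. Within the array set that holds naive, iTreg and nTreg, 8 of 18 tests passed. Gata3 in Th1 was at -0.32 ± 0.12 (SE) and lay at 0.04 with arrays scaled to one median and at 0.65 with the deposited scaling. Leaving out naive replicate 2 put it at -0.25, and leaving out Th1 replicate 1 put it at -0.16, neither past the test. Gata3 in Th17 was at -0.87 ± 0.12 (SE), and at 0.10 with the deposited scaling. Leaving out naive replicate 2 ended the calls of Il10 in Th17 (0.71 in place of 0.96) and of Tbx21 in nTreg (0.52 in place of 0.72). Leaving out Th17 replicate 1 also ended the call of Il10 in Th17 (0.59). Il4 in iTreg, at -0.83 ± 0.33 (SE), kept its call in 12 of 24 alternatives.

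**Figure D2:**
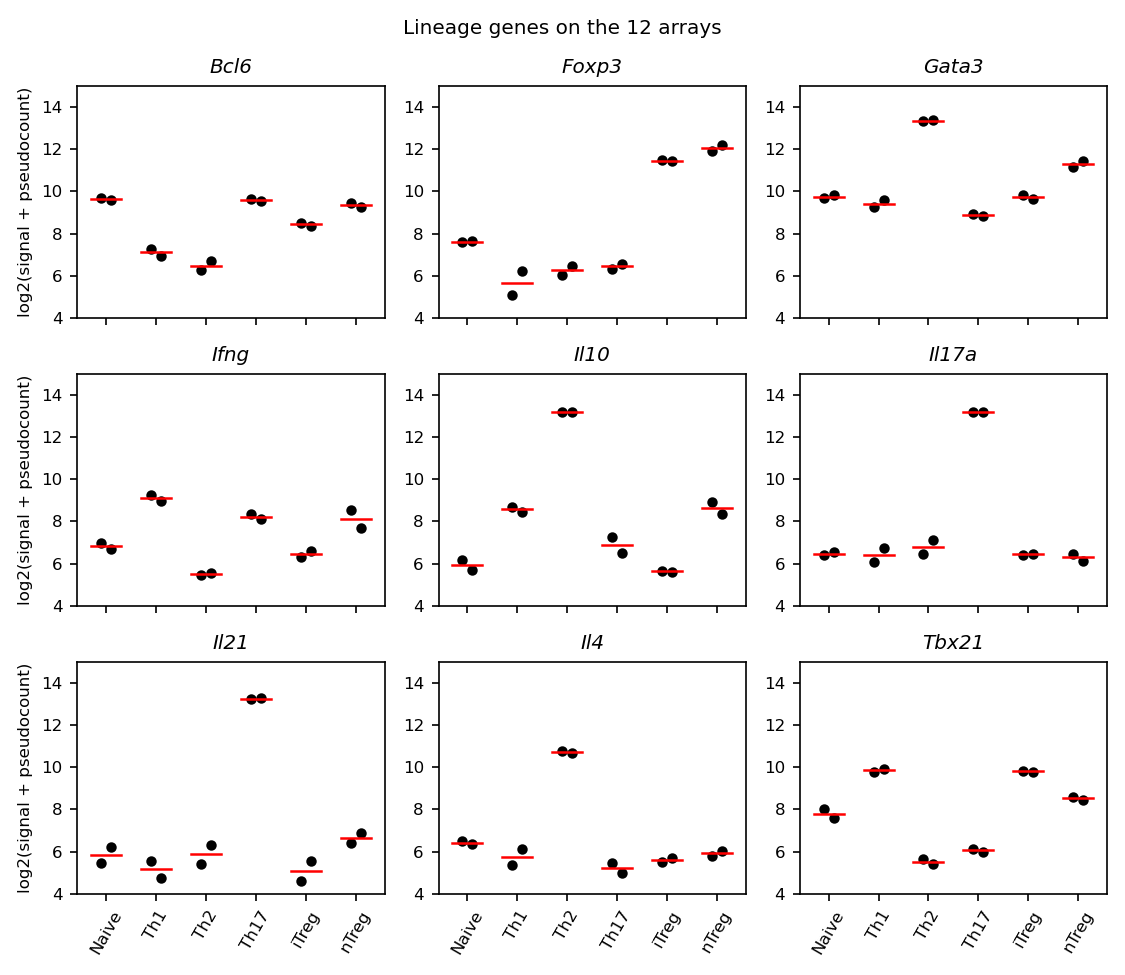
Log2(signal + pseudocount) of 9 lineage genes on the 12 arrays by group, with 1 point per array and a red line at the mean of 2 arrays. Il17a and Il21 stand at 13.2 in Th17, Gata3 at 13.3 in Th2, and Tbx21 at 9.84 in Th1 and 9.80 in iTreg.

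Cultured cells differed from naive cells in genes of growth and division. All 28 measured members of the cell cycle list were higher in the mean of Th1, Th2, Th17 and iTreg (8 arrays) than in naive cells (2 arrays), among them Ccnb2, a mitotic cyclin, 24.4-fold (log2 4.61 ± 0.11 SE) and Birc5, which encodes survivin, 16.6-fold. All 16 genes of the glycolysis list were higher, with Egln3, an oxygen sensor, at 31.5-fold and Tpi1, triosephosphate isomerase, at 9.81-fold. So were all 14 cholesterol synthesis genes, such as Fdps at 5.81-fold and Hmgcs1 at 4.55-fold. Of 18 genes of the naive and quiescent state, 17 were lower, including Dapl1 at 121-fold, Klf3 at 24.9-fold and Klf2, which controls lymphocyte trafficking, at 10.2-fold. The largest single rises were AA467197 at 145-fold (log2 7.18 ± 0.17 SE), S100a4, a calcium-binding protein, at 103-fold, Ctla2a at 81.4-fold, Lgals3, which encodes galectin-3, at 70.9-fold, the metallothionein Mt1 at 61.6-fold, Ctla2b at 47.2-fold, Socs2 at 40.9-fold and Fgl2 at 37.5-fold. The largest falls were Hspa1b at 200-fold (log2 -7.64 ± 0.23 SE) and Hspa1a at 64.6-fold, both encoding the inducible heat shock protein Hsp70. Erdr1, St8sia6, Ifi213, Ampd1 and Pdlim4 were 36.0-fold, 35.3-fold, 33.8-fold, 32.8-fold and 27.6-fold lower. Within the array set, in iTreg against naive cells, all 16 of these genes passed in the same direction, but Erdr1 was only 2.00-fold lower, Fgl2 1.90-fold higher and S100a4 8.96-fold higher. Other changes shrank too, such as those of Dapl1 to 11.3-fold, St8sia6 to 6.44-fold, Lgals3 to 17.9-fold and AA467197 to 42.5-fold. Only Socs2, Ifi213 and Ampd1 changed more there, by 78.0-fold, 83.8-fold and 38.5-fold.

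The counts adjusted over the list alone were the same for cell cycle (28), glycolysis (16), cholesterol synthesis (14) and the naive state (17 lower, 1 higher). Camera gave adjusted p = 8.0e-19, 4.56e-13, 2.5e-09 and 6.81e-10 for these lists, with 9 of 17 lists past the test. Of 20 interferon response genes 12 were lower, such as Usp18 at 7.17-fold and Ifit1 at 7.00-fold, 4 were higher and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.00413, and adjusted p = 0.0750 with an estimated correlation), and the list's median of -0.87 was -0.15 with the deposited scaling. Of 26 chromatin modifiers 17 were lower, such as the methyltransferase gene Kmt2a at 3.41-fold, 4 were higher, such as Ezh2 at 3.26-fold and Uhrf1 at 9.30-fold, and 5 did not pass, with the same counts when adjusted over the list alone. As a list the chromatin modifiers did not pass (median log2 -0.42, camera adjusted p = 0.0796), and their median was 0.31 with the deposited scaling. They passed with quantile normalization (adjusted p = 0.0419), and within the array set of naive cells 9 were higher and 11 lower (median -0.11, adjusted p = 0.788), with adjusted p from 0.0419 to 0.788 over 25 alternatives with camera.

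Of the 4 cultured groups only iTreg shares an array set with naive cells. In all, 7809 genes differed between cultured and naive cells, 3637 higher and 4172 lower, and 2924 of them by at least 2-fold, 1425 higher and 1499 lower (limma, Benjamini-Hochberg). In iTreg against naive cells alone, which share an array set, 7149 genes passed, and 70.0% of the 7809 kept their call and sign. The naive arrays stood apart in hybridisation controls within that set, so these values are not free of array differences. In iTreg against naive cells all 28 cell cycle and all 14 cholesterol genes were again higher. Of 16 genes of the glycolysis list 14 were higher and 1 lower, and 15 of 18 genes of the naive state were lower. The share of higher calls, 46.6%, was 72.4% with arrays scaled to one median, which moved the median of all genes from -0.08 to 0.30. It was 85.5% with the deposited scaling, which by construction moved that median up, to 0.61.

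The Th1 arrays were set apart by receptor and effector genes shared with natural killer cells. Klrc1 was 104-fold higher in Th1 than in the mean of Th2, Th17 and iTreg (log2 6.70 ± 0.17 SE, 2 against 6 arrays), Klrk1, which encodes NKG2D, 83.4-fold, Klra5 71.8-fold and Klrd1, which encodes CD94, 28.2-fold. Plac8, the granzyme gene Gzmc, the interferon-induced gene Ifitm1 and Emilin2 were 49.5-fold, 32.5-fold, 32.1-fold and 25.4-fold higher. Of 18 Th1 programme genes 15 were higher and 3 lower, with Fasl at 24.9-fold, the chemokine receptor gene Cxcr3 at 21.8-fold and Il12rb2, a chain of the interleukin-12 receptor, at 13.9-fold. Of 20 interferon response genes 18 were higher and 2 did not pass, with Iigp1 at 7.09-fold and Gbp2 at 5.6-fold. Penk, encoding proenkephalin, was 46.2-fold lower in Th1 (log2 -5.53 ± 0.15 SE), Cyp11a1, the enzyme that starts steroid synthesis, 42.8-fold, Spsb1 21.5-fold, Cpd 17.3-fold, Ccr6 11.4-fold, Ldlrad4 11.0-fold, Il6ra 10.7-fold and Egr3 9.02-fold.

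Of 9 CD8 and NK marker genes 6 were higher in Th1 and 3 did not pass, and Gzma was 38.1-fold higher. Whether Th1 cells or other cells in the Th1 cultures carried these transcripts was not tested. Of 12 TGF-beta response genes 8 were lower, such as Pmepa1 at 7.21-fold and Itgae at 4.50-fold, and 4 did not pass. Camera gave adjusted p = 2.52e-11 for the Th1 programme, 5.81e-16 for interferon response, and 5.53e-06 for both CD8 and NK markers and TGF-beta response, with 5 of 17 lists past the test. Adjusted over the list alone, 15 Th1 programme genes were higher and 3 lower, 18 interferon genes and 6 CD8 and NK markers were higher, with 1 such marker lower, and 9 TGF-beta response genes were lower. Of 11 Tfh programme genes 9 were lower and 2 higher, also when adjusted over the list alone, with Cd200 at 5.69-fold and Tox2 at 4.52-fold lower (camera adjusted p = 0.00753, and adjusted p = 0.0625 with an estimated correlation). Of 16 Th17 programme genes 11 were lower, 4 higher and 1 not past the test, with the same counts of 11 and 4 when adjusted over the list alone. Ccr6 was among the lower ones, while Tmem176a and Tmem176b were 7.15-fold and 7.20-fold higher, and the list did not pass (median log2 -1.53, camera adjusted p = 0.0699). It passed as lower in 7 of 25 alternatives with camera, among them the comparison within the array set (median -0.97, adjusted p = 0.000494; 2 higher and 11 lower), the deposited scaling (adjusted p = 0.000191) and the leaving out of Th1 replicate 1 (median -1.46, adjusted p = 0.0472), with adjusted p from 0.000191 to 0.174.

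In Th1, 4622 genes passed, 1865 higher and 2757 lower, and 1061 by at least 2-fold, 563 higher and 498 lower. Against Th2 and Th17 alone, which share its array set, 3707 genes passed, and 55.9% of the 4622 genes both still passed and kept their sign. In that set 13 Th1 programme genes were higher and none was lower, 17 interferon genes were higher and 9 TGF-beta response genes were lower. The share of higher calls, 40.4%, was 82.4% with the deposited scaling, which by construction moved the median of all genes up, from -0.07 to 0.24.

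Th2 cells carried their cytokines at high levels. Il5 was 93.6-fold higher in Th2 than in the mean of Th1, Th17 and iTreg (log2 6.55 ± 0.39 SE, 2 against 6 arrays), Il10 70.8-fold, Il13 51.1-fold and Il4 36.7-fold. Pth, encoding parathyroid hormone, was 118-fold higher (log2 6.88 ± 0.40 SE), Cyp11a1 118-fold, Rnf128, the ubiquitin ligase GRAIL of unresponsive T cells, 117-fold and the myosin gene Myo6 112-fold. Of 16 Th2 programme genes 12 were higher, 2 lower and 2 not past the test. Lta, encoding lymphotoxin alpha, was 42.5-fold lower (log2 -5.41 ± 0.09 SE), Ncf1, a subunit of the phagocyte oxidase, 28.1-fold, Gpr18 27.5-fold, Nt5e, which encodes the ectonucleotidase CD73, 27.0-fold, and the lymph node homing receptor gene Ccr7 24.3-fold. Xdh, Ipcef1 and Il18r1 were 20-fold, 20-fold and 19.4-fold lower.

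Of 18 genes of the naive state 14 were lower in Th2, such as Igfbp4 at 13.9-fold and Actn1 at 9.17-fold, 2 were higher and 2 did not pass. Of 18 Th1 programme genes 13 were lower, such as Tbx21 at 8.23-fold and Ccl3 at 8.14-fold, 4 did not pass, and the granzyme gene Gzmb was higher at 13.7-fold. Of 20 interferon response genes 16 were lower, such as Iigp1 at 13.3-fold and Gbp2 at 7.64-fold, 2 were higher and 2 did not pass. Of 11 Tfh programme genes 8 were lower, such as Cd200 at 7.27-fold and Btla at 5.38-fold, 1 was higher and 2 did not pass. Camera gave adjusted p = 1.43e-10 for the Th2 programme, 2.21e-07 for the naive state, 3.2e-06 for the Th1 programme, 1.41e-06 for interferon response and 6.38e-05 for the Tfh programme, with 8 of 17 lists past the test. Adjusted over the list alone, 12 Th2 programme genes were higher and 2 lower, and 14, 13, 16 and 10 genes of the naive, Th1, interferon and Tfh lists were lower.

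In Th2, 4561 genes passed, 1906 higher and 2655 lower, and 1190 by at least 2-fold, 563 higher and 627 lower. Against Th1 and Th17 alone, 4397 genes passed, and 64.8% of the 4561 genes both still passed and kept their sign. There 12 Th2 programme genes were higher and 1 lower. Higher calls made up 41.8%, against 80.6% with the deposited scaling, which by construction moved the median of all genes up, from -0.06 to 0.25.

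Th17 cells were led by their cytokines and by genes also known from follicular helper cells. Il21 was 235-fold higher in Th17 than in the mean of Th1, Th2 and iTreg (log2 7.88 ± 0.34 SE, 2 against 6 arrays) and Il17a 102-fold (log2 6.67 ± 0.22 SE). Tgm2, a transglutaminase, Serpinb1a, the interleukin-1 receptor gene Il1r1, Gpr15, Tox2 and Ermn were 36.4-fold, 26.2-fold, 25.2-fold, 21.4-fold, 18.2-fold and 16.8-fold higher. Of 16 Th17 programme genes 12 were higher and 4 lower, and of 11 Tfh programme genes 8 were higher, including Slamf6 at 5.01-fold and Bcl6 at 4.77-fold, 1 was lower and 2 did not pass. Of 28 cell cycle genes 25 were lower in Th17 and 3 did not pass, with Cdk1 at 2.30-fold and the replication helicase gene Mcm5 at 2.23-fold. Nkg7, a cytotoxic granule protein, was 12.6-fold lower (log2 -3.65 ± 0.12 SE), Drc1 11.8-fold, Epas1, which encodes the hypoxia factor HIF-2 alpha, 10.4-fold, Plxdc2 6.88-fold, Rtp4 6.67-fold, Spry1 6.20-fold, Klf2 6.16-fold and Entpd1 6.07-fold.

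Of 18 genes of the naive state 14 were higher in Th17, such as Ccr7 at 10.8-fold and Il7r at 6.91-fold, and 4 were lower, also when adjusted over the list alone (camera adjusted p = 3.33e-05, and adjusted p = 0.0712 with an estimated correlation). Of 12 TGF-beta response genes 8 were higher, such as Tgfbi at 3.25-fold and Itgae at 3.13-fold, 1 was lower and 3 did not pass, with 8 and 1 when adjusted over the list alone (camera adjusted p = 0.0266, and adjusted p = 0.0816 with an estimated correlation). Of 16 Th2 programme genes 11 were lower, 1 higher and 4 not past the test, and of 14 cholesterol synthesis genes 13 were lower, such as Idi1 at 1.76-fold, and 1 did not pass. Camera gave adjusted p = 1.9e-05 for the Th17 programme, 1.63e-06 for both the Tfh programme and cholesterol synthesis, 1.39e-13 for cell cycle and 9.6e-05 for the Th2 programme, with 14 of 17 lists past the test. Adjusted over the list alone, 12 Th17 and 8 Tfh genes were higher, and 26 cell cycle, 14 cholesterol synthesis and 11 Th2 programme genes were lower. Cholesterol synthesis and cell cycle had medians of -0.46 and -0.78, and of -0.13 and -0.45 with the deposited scaling. TGF-beta response, at 0.46, was at 0.81 there and did not pass (adjusted p = 0.055, and 0.000299 to 0.0816 over 25 alternatives with camera).

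Some B cell markers and some myeloid and dendritic markers were also higher in Th17, while of 9 CD8 and NK markers 2 were higher, 4 lower and 3 not past the test. Of 12 B cell markers 7 were higher, such as H2-Aa at 3.55-fold, and 5 did not pass (camera adjusted p = 0.0203, and adjusted p = 0.0755 with an estimated correlation). Of 13 myeloid and dendritic markers 7 were higher, such as Clec7a at 4.21-fold, and 6 did not pass (camera adjusted p = 0.0148, and adjusted p = 0.120 with an estimated correlation). For the B cell list and the myeloid and dendritic list the counts adjusted over the list alone were the same. Against Th1 and Th2 alone 6 and 5 of these markers were higher and none was lower, but neither list passed there (medians 0.68 and 0.58, adjusted p = 0.0573 and 0.0685). Over their 25 and 24 alternatives with camera adjusted p ranged from 0.00105 to 0.232 and from 0.000315 to 0.232, highest with the deposited scaling.

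In Th17, 5179 genes passed, 2783 higher and 2396 lower, and 1106 by at least 2-fold, 714 higher and 392 lower. Against Th1 and Th2 alone, 5032 genes passed, and 69.9% of the 5179 genes both still passed and kept their sign. In that set 11 Th17, 10 Tfh and 0 cell cycle genes were higher and 27 cell cycle genes were lower, while 6 of 14 cholesterol synthesis genes were lower (median log2 -0.16 in place of -0.46). The share of higher calls, 53.7%, was 22.2% with arrays scaled to one median, which moved the median of all genes from 0.04 to -0.24. It was 85.6% with the deposited scaling, which by construction moved that median up, to 0.36.

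In iTreg the regulatory gene Foxp3 was 40.3-fold higher than in the mean of Th1, Th2 and Th17 (log2 5.33 ± 0.23 SE, 2 against 6 arrays). Nr4a3, an orphan nuclear receptor induced by T cell receptor signals, was 163-fold higher (log2 7.35 ± 0.12 SE), Lad1 64.1-fold, the cytokine gene Il9 60-fold, Dusp4, a phosphatase of MAP kinases, 49.3-fold and Plagl1 38.2-fold. Gzma, encoding granzyme A, was 264-fold lower (log2 -8.04 ± 0.19 SE), the chemokine receptor gene Ccr2 216-fold, S100a6 138-fold, the leukotriene receptor genes Ltb4r1 98.6-fold and Cysltr1 67.5-fold, Ifitm1 90.9-fold and the nuclear RNA Malat1 56.7-fold. Erdr1 and the Y-linked Eif2s3y were 47.1-fold and 38.2-fold higher and Xist 397-fold lower. Of these 16 genes 15, all but Il9, lay on the same side of the mean of Th1, Th2 and Th17 in both naive and nTreg arrays, among them Nr4a3 at log2 10.06 and 10.72 against 6.16, with 13.51 in iTreg. For 8 of the 16, Nr4a3, Lad1, Il9, Dusp4, Xist, Gzma, Ccr2 and Malat1, iTreg also lay beyond both naive and nTreg in the same direction. Of 23 Treg programme genes 13 were higher, such as Gpr83 at 21.2-fold, 8 were lower, such as Fgl2 at 53.3-fold and Il10 at 15-fold, and 2 did not pass, with the same counts of 13 and 8 when adjusted over the list alone. The list did not pass as a whole (median log2 0.57, camera adjusted p = 0.327), but with the deposited scaling it passed as higher than the other genes (adjusted p = 0.00258), at a median of -0.43 where that of all genes was -0.84. Over its 24 alternatives with camera adjusted p ranged from 0.00258 to 0.736. Against naive cells of the same array set, 19 of the 23 genes were higher in iTreg and 2 lower, with a median log2 of 2.05. The subsets set against iTreg also differed on this list. In Th17 3 of its genes were higher and 16 lower than in the other cultured subsets, and in Th2 12 were higher and 5 lower.

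Of 12 TGF-beta response genes 8 were higher in iTreg, 2 lower and 2 not past the test, with Pmepa1 at 7.19-fold and Tgfbr1 at 4.62-fold higher (camera adjusted p = 0.02, and adjusted p = 0.123 with an estimated correlation). All 14 cholesterol synthesis genes were higher, such as Dhcr7 at 4.51-fold and Cyp51 at 3.40-fold (camera adjusted p = 6.61e-06, and adjusted p = 0.106 with an estimated correlation). Of 28 cell cycle genes 24 were higher, such as Aurkb at 2.55-fold, 2 were lower, such as Cenpe at 2.64-fold, and 2 did not pass (camera adjusted p = 6.61e-06, and adjusted p = 0.258 with an estimated correlation). Of 9 CD8 and NK markers 6 were lower and 3 did not pass (camera adjusted p = 0.00395, and adjusted p = 0.106 with an estimated correlation). Of 18 immediate early genes 8 were higher, such as Egr2 at 11.0-fold and Nr4a1 at 10.7-fold, 5 were lower, such as Fos at 9.73-fold, and 5 did not pass, and the list did not pass (camera adjusted p = 0.370, median log2 0.47). With the deposited scaling its median was -0.50 and it passed as higher than the other genes (adjusted p = 0.0121, and 0.0121 to 0.736 over 24 alternatives with camera). With the deposited scaling, where the median of all genes was -0.84, the medians of the TGF-beta, cholesterol and cell cycle lists went from 1.15, 1.03 and 0.95 to 0.25, 0.044 and -0.04, still higher than the other genes past the test. That of the CD8 and NK markers went from -1.06 to -1.96 and no longer passed (adjusted p = 0.195, and 0.000156 to 0.195 over 24 alternatives with camera). The counts adjusted over the list alone were 8 and 2 for TGF-beta response, 14 for cholesterol synthesis, 24 and 2 for cell cycle, 6 lower for CD8 and NK markers, and 8 and 5 for the immediate early genes. In all, 6 of 17 lists passed, and 0 of the 6 with an estimated correlation.

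In iTreg, 7469 genes passed, 4166 higher and 3303 lower, and 2719 by at least 2-fold, 1325 higher and 1394 lower. No value within an array set can be had, so array set, donor sex and subset cannot be told apart for these genes. Of the higher genes 2107, or 50.6%, were also higher in iTreg than in both naive and nTreg cells of the same array set, and of the lower genes 1703, or 51.6%, were also lower than in both. The share of higher calls, 55.8%, was 75.4% with arrays scaled to one median, which moved the median of all genes from 0.07 to 0.40. It was 7.92% with the deposited scaling, which by construction moved that median down, to -0.84.

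In nTreg all 23 Treg programme genes were higher than in naive cells. Itgae, the integrin CD103, was 186-fold higher (log2 7.54 ± 0.29 SE, 2 arrays each), Nrp1, a surface marker of thymus-derived regulatory cells, 36.3-fold, Fgl2, a secreted suppressive protein, 35.6-fold and Klrg1 24.9-fold. The largest rise was S100a4 at 270-fold (log2 8.08 ± 0.19 SE), and Tiam1, S100a6, the transcription factor gene Maf and Ttc39c were 46.7-fold, 37.8-fold, 33.6-fold and 28.3-fold higher. Of 13 chemokine receptor genes 8 were higher, such as Cxcr3 at 25.9-fold, Ccr2 at 16.4-fold and Cxcr5 at 10.9-fold, 1 was lower and 4 did not pass. Cytokine genes were among the largest falls, with Csf2 21.8-fold lower (log2 -4.44 ± 0.29 SE) and Il2 14.9-fold lower. Pdlim4, Lbp, Hs3st3b1, Pde3b, Dapl1 and Cnga1 were 26.6-fold, 18.4-fold, 16.3-fold, 14.6-fold, 14.5-fold and 13.1-fold lower.

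Of 16 Th17 programme genes 11 were higher in nTreg and 5 did not pass, and the members that rose were led by Maf, the aryl hydrocarbon receptor gene Ahr at 10.1-fold and Ccr6 at 9.28-fold. Of 12 TGF-beta response genes 9 were higher, 1 lower, Tgfbr3 at 3.82-fold, and 2 not past the test. Of 18 genes of the naive state 11 were lower, such as Igfbp4 at 3.25-fold and Satb1 at 2.84-fold, 4 higher and 3 not past the test (camera adjusted p = 0.000158, and adjusted p = 0.0979 with an estimated correlation). Camera gave adjusted p = 1.38e-28 for the Treg programme, 7.89e-08 for the Th17 programme, 8.52e-05 for chemokine receptors and 0.00027 for TGF-beta response, with 11 of 17 lists past the test. Adjusted over the list alone, 23 Treg, 11 Th17, 9 chemokine receptor and 9 TGF-beta response genes were higher, and 11 genes of the naive state were lower and 5 higher.

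Some markers of other cells moved with nTreg, while of 9 CD8 and NK markers 2 were higher, 2 lower and 5 not past the test. Of 12 B cell markers 8 were higher and 4 did not pass, with H2-Eb1 and H2-Aa of MHC class II at 9.68-fold and 9.47-fold, its invariant chain Cd74 at 8.84-fold and Cd79b at 8.27-fold (camera adjusted p = 0.000416). Of 13 myeloid and dendritic markers 6 were higher and 7 did not pass, with Cybb at 18.4-fold and Fcer1g at 8.42-fold (camera adjusted p = 0.0102, and adjusted p = 0.151 with an estimated correlation). When adjusted over the list alone, 8 B cell markers and 7 myeloid and dendritic markers were higher. Of the erythroid markers only Car1 was tested, and it was higher by log2 1.90. Of 18 immediate early genes 7 were higher, such as Dusp1 at 5.59-fold, 3 lower and 8 not past the test, with 9 and 3 when adjusted over the list alone (camera adjusted p = 0.0483, and adjusted p = 0.438 with an estimated correlation). Without nTreg replicate 1 that list's median went from 0.47 to -0.03 with adjusted p = 0.675, and over its 25 alternatives with camera adjusted p ranged from 1.48e-05 to 0.675.

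In nTreg, 4375 genes passed against naive cells, 2592 higher and 1783 lower, and 1382 by at least 2-fold, 928 higher and 454 lower. With only the 6 arrays of their set in the fit, 3610 passed, 81.0% of the 4375 genes still passed, and all 23 Treg programme genes stayed higher. The fold changes are the same in both fits, which differ only in the estimate of spread. Both fits use the naive arrays, which stood apart in hybridisation controls. Higher calls made up 59.2%, against 87.9% with arrays scaled to one median, which moved the median of all genes from 0.01 to 0.30.

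iTreg and nTreg, both Foxp3-positive populations of one array set, differed in growth genes and in parts of the Treg programme. iTreg had been cultured for 10 days and nTreg had not, so culture and kind of regulatory cell cannot be told apart here. All 28 cell cycle and all 14 cholesterol synthesis genes were also higher in cultured than in naive cells. Foxp3 itself differed by log2 -0.61 ± 0.28 (SE, 2 arrays each, adjusted p = 0.0813). All 28 cell cycle genes were higher in iTreg, such as Ube2c at 31.6-fold (log2 4.98 ± 0.23 SE) and Aurkb at 21.9-fold, and so were all 14 cholesterol synthesis genes, such as Cyp51 at 10.4-fold. Of 23 Treg programme genes 14 were lower in iTreg, including Klrg1 at 74.8-fold, Itgae at 38.2-fold and Ikzf2, which encodes Helios, at 24.0-fold, 4 were higher and 5 did not pass. Scd1, a fatty acid desaturase, was 121-fold higher in iTreg (log2 6.92 ± 0.15 SE), the stress gene Nupr1 85.8-fold, Akr1c18 68.6-fold, AA467197 66.4-fold, Kctd14 51-fold, the cell cycle inhibitor gene Cdkn1a 50.8-fold, Il9 42.2-fold and Fbxo2 32.3-fold. Hspa1b and Hspa1a were 125-fold (log2 -6.97 ± 0.29 SE) and 68.6-fold lower, Ifi209 95.1-fold, Jchain, the joining chain of secreted antibodies, 57.8-fold, Ifit1bl1 50.9-fold, Fos 43.6-fold and Pglyrp1 43.6-fold.

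Of 16 genes of the glycolysis list 13 were higher in iTreg, such as Bnip3 at 9.83-fold, 2 were lower and 1 did not pass. Of 20 interferon response genes 15 were lower, such as Gbp3 at 15.5-fold, 4 were higher and 1 did not pass (camera adjusted p = 0.00169, and adjusted p = 0.0658 with an estimated correlation). Of 18 genes of the naive state 13 were lower, such as Il7r at 38.6-fold, 3 were higher and 2 did not pass (camera adjusted p = 0.00591, and adjusted p = 0.187 with an estimated correlation). Of 12 B cell markers 8 were lower, such as H2-Aa at 19.3-fold, and 4 did not pass (camera adjusted p = 0.00933, and adjusted p = 0.0679 with an estimated correlation), and of 13 myeloid and dendritic markers 8 were lower, such as Cybb at 29.4-fold, and 5 did not pass (camera adjusted p = 0.00979, and adjusted p = 0.171 with an estimated correlation). Camera gave adjusted p = 2.31e-19 for cell cycle, 1.8e-10 for cholesterol synthesis and 2.06e-07 for glycolysis, with 9 of 17 lists past the test. For the Treg programme it gave adjusted p = 0.0026, and adjusted p = 0.211 with an estimated correlation. The counts adjusted over the list alone were the same for all 8 of these lists.

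Between iTreg and nTreg 6998 genes passed, 3276 higher and 3722 lower in iTreg, and 3207 by at least 2-fold, 1403 higher and 1804 lower. With only the 6 arrays of their set in the fit, 6576 passed and 92.7% of the 6998 genes still passed, with the same fold changes. Higher calls made up 46.8%, against 68.0% with arrays scaled to one median, which moved the median of all genes from -0.07 to 0.28.

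The last comparison set the change from naive cells to nTreg against the change from Th1, Th2 and Th17 to iTreg. Foxp3 was raised in both, and the difference between the 2 changes was -0.89 ± 0.37 on the log2 scale (SE, adjusted p = 0.0556). Without Th1 replicate 1, Th1 replicate 2 or Th2 replicate 2 it was -0.71, -1.08 and -0.96 and passed, and over its 23 alternatives adjusted p ranged from 0.00271 to 0.740. Of 23 Treg programme genes, all higher in nTreg than in naive cells, 19 had a positive difference. Of these 8 were lower in iTreg than in Th1, Th2 and Th17, such as Fgl2 with a difference of 10.89 ± 0.17 (SE) and Il10 with 6.60 ± 0.34 (SE), 9 were higher, such as Itgae with 6.45 ± 0.37 (SE), and 2 did not pass in iTreg. For 3 genes, Gpr83, Nt5e and Izumo1r, the change was larger in iTreg, by -0.73 ± 0.26, -0.72 ± 0.15 and -0.32 ± 0.11 (SE), and 1 did not pass. The largest differences were 12.77 for S100a4, 12.35 for S100a6 and 11.79 for Ccr2, all higher in nTreg than in naive cells and lower in iTreg than in the other cultured subsets. Dapl1, Il2 and Erdr1 had the largest differences the other way, at -8.42, -7.57 and -6.94.

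Adjusted over the list alone, 19 Treg programme genes had a positive difference and 4 a negative one (camera adjusted p = 8.89e-11, and adjusted p = 0.0728 with an estimated correlation), with 10 of 17 lists past the test and 0 of the 10 with an estimated correlation. Markers of other cells had positive differences too: 6 of 12 B cell markers, such as H2-Aa at 4.30 (camera adjusted p = 0.00994, and adjusted p = 0.0809 with an estimated correlation), and 8 of 13 myeloid and dendritic markers, such as Cybb at 5.28 (camera adjusted p = 0.00872, and adjusted p = 0.137 with an estimated correlation). The others did not pass, and adjusted over the list alone 6 and 10 were positive and 1 of each list was negative. Neither list passed with the deposited scaling (adjusted p = 0.546 and 0.451, the highest of ranges that began at 0.0022 for both, over 24 and 23 alternatives with camera). A further probe set of Socs2, a member at 2.73, had a difference of -1.33. The calls of Gpr83 and Izumo1r ended under 9 and 7 of 23 alternatives, among them the leaving out of naive replicate 1, of either iTreg array or of nTreg replicate 1, and Gpr83 also without nTreg replicate 2, and Nt5e and Izumo1r were at 0.17 and 0.66 with the deposited scaling. In all 6263 genes had different changes, 3036 positive and 3227 negative, and 3149 by at least 2-fold. The positive share, 48.5%, was 93.1% with the deposited scaling, which by construction moved the median of all genes up, from -0.07 to 0.86. Array set and donor sex cannot be told apart from the iTreg side of this difference. The lists of calls compare no arrays in common but rest on the same estimate of spread for each gene. They held 1196 genes higher in both nTreg and iTreg and 676 lower in both. Independent lists would share 873 and 476, or 1000 and 526 when computed within 10 groups of genes of like mean signal, since bright genes were called more often in both. These numbers do not allow for the shared estimate of spread, by which genes of low spread are called more readily in both lists.

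**Figure D3:**
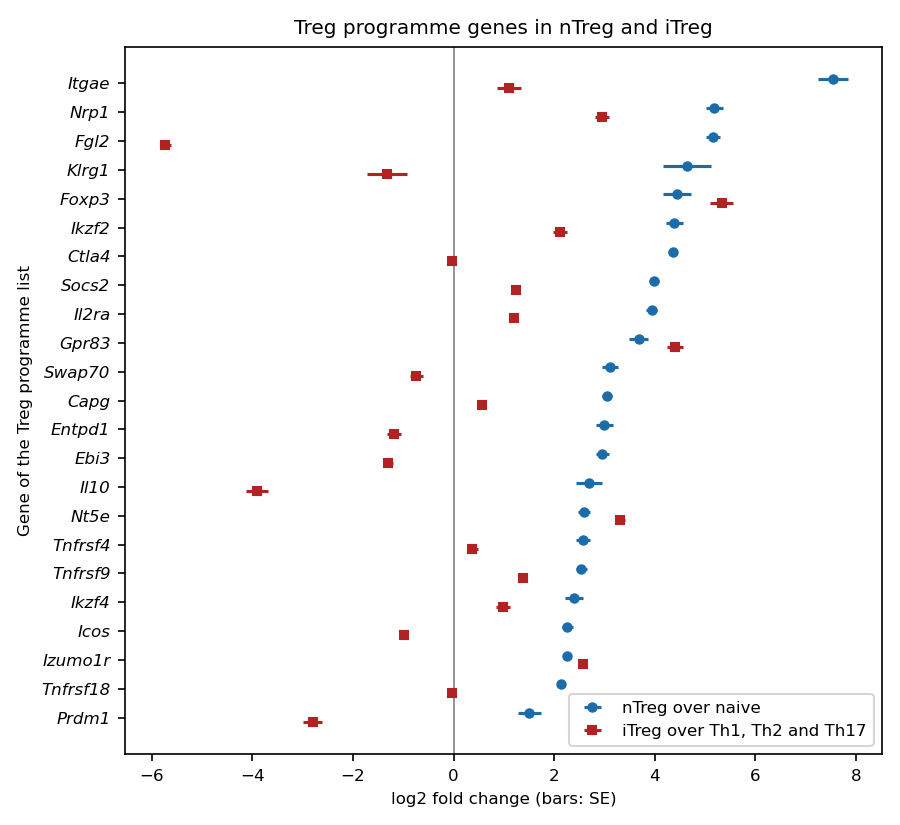
Log2 fold changes, with SE bars, of the 23 measured Treg programme genes in nTreg over naive cells (blue circles) and in iTreg over the mean of Th1, Th2 and Th17 (red squares). All 23 lie above 0 in nTreg, and in iTreg they run from -5.74 for Fgl2 to 5.33 for Foxp3. With the deposited scaling, which by construction lowers iTreg against Th1, Th2 and Th17, the median of the list in iTreg is below 0.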

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

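The tests for Th1 cells in the iTreg cultures, both tests for the array set behind Tbx21 and the test for B cells among nTreg were chosen after the result was seen.

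The change from naive cells to nTreg differed from the change from Th1, Th2 and Th17 to iTreg, by a test of the difference itself, in 6263 genes, and the genes given next drew attention for that. The largest positive differences (log2) were 12.77 for S100a4, 12.35 for S100a6, 11.79 for Ccr2, 10.89 for Fgl2, 8.94 for Gzma, 8.54 for Anxa1, 8.52 for Ltb4r1 and 8.31 for Myo1f. The largest negative ones were -8.42 for Dapl1, -7.57 for Il2, -6.94 for Erdr1, -6.70 for Nr4a3, -6.66 for Pdlim4, -6.11 for Ccl3, -6.03 for Cth and -5.90 for Atp1b1. In the Treg programme the differences were 6.60 for Il10, 6.45 for Itgae, 5.97 for Klrg1, 4.38 for Ctla4, 4.31 for Prdm1, 4.26 for Ebi3, 4.18 for Entpd1, 3.85 for Swap70, 3.26 for Icos, 2.75 for Il2ra, 2.73 for Socs2, 2.48 for Capg, 2.27 for Ikzf2, 2.24 for Nrp1, 2.20 for Tnfrsf4, 2.15 for Tnfrsf18, 1.41 for Ikzf4 and 1.16 for Tnfrsf9. They were -0.73 for Gpr83, -0.72 for Nt5e and -0.32 for Izumo1r. Poly-A spike controls drew attention as a signal outside every comparison, with a median signal of 354.7 on the Th1, Th2 and Th17 arrays and 7.76 on the others.

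The 7469 genes called in iTreg against Th1, Th2 and Th17 may reflect array set or donor sex in place of the subset. For 2545 of them, or 34.07%, naive and nTreg arrays both lay on the same side as iTreg past the test. A share under 50% was set in advance as speaking against array set or sex, yet it does not decide here. Naive and nTreg cells were not cultured, so a culture effect would move them away from iTreg whatever the array set did. The design keeps array set, donor sex and subset from being told apart, and subset stays an untested biological explanation.

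Tbx21 differed between iTreg and Th1 by -0.05, but by -1.03 with the deposited scaling (adjusted p = 0.000583). That scaling sets the array sets 2-fold apart by construction, so its value cannot speak against the closeness. Over the others of the 23 alternatives added later the difference was -0.11 to 0.27. As the 2 groups lie on different array sets, the array set stays open for this closeness. Th1 cells in the iTreg cultures would bring their other transcripts. Over the 30 genes most raised in Th1 against Th2 and Th17, however, the median difference of iTreg from Th1 was -3.76 (quartiles -5.22 to -2.44), with 0 genes higher in iTreg. These genes were picked for high values on the same Th1 arrays, which favours lower values in iTreg, and this difference too crosses the array sets. The array set alone would not set iTreg apart from nTreg and naive cells of its own set, where Tbx21 was higher in iTreg by 1.28 (adjusted p = 0.000257) and 1.99 (adjusted p = 1.05e-05). A single off-target probe set stays open, since 0 other probe sets were named for Tbx21, and transcription of Tbx21 by iTreg stays untested.

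Of 12 B cell markers, MHC class II included, 8 were higher in nTreg than in naive cells, as were 6 of 13 myeloid and dendritic markers, a list not past the test with an estimated correlation (adjusted p = 0.151, and 0.000205 to 0.151 over 24 alternatives with camera). B cells or myeloid cells in the CD25hi CD4+ fraction are candidate sources. The 8 B cell genes outside MHC class II, without Ighm, had a median log2 change of 0.40 (quartiles -0.15 to 1.32), 3 over 1 and 3 below 0. Of these 8, 6 were bright enough to be tested, and Cd79b was the most abundant at log2 9.45 in nTreg. Ighm, left out of this set, was among the B cell markers higher in nTreg. Over 28 neutrophil and macrophage genes, 24 of them bright enough to be tested in these T cells and 3 held by another list, the median was 0.40 (quartiles -0.16 to 1.48), 12 over 1 and 9 below 0, with Ms4a6c at 11.58 and Cst3 at 11.48 in nTreg, and 12.24 and 11.22 in naive cells. The largest rises were 3.18 for S100a9, 2.88 for S100a8 and 2.30 for Mpeg1, and the largest fall was -0.765 for Cxcr2. The median of this list is under the 0.5 set in advance as speaking against myeloid cells, but members went both ways and spread past it, so neither source is excluded. MHC class II genes had a median of 3.14, and their transcription by nTreg stays untested.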

How the results depend on the processing

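The deposited scaling, the comparisons within an array set and the alternatives for Tbx21 in iTreg against Th1 were chosen after the data were seen.

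Of 345 named gene results past the test, 328 kept their call and direction under every alternative chosen beforehand, the leaving out of each array included, and within an array set 240 of 243 did. Many of these genes were named for large changes past the test, so their stability was in part fixed by that choice. The count within a set includes nTreg against naive and iTreg against nTreg, where the fold changes are the same. Over all genes past the test, 55.9% to 70.0% kept their call and sign where the arrays compared changed. Of the described list results, which were chosen after they were seen, 47 passed the test. Of these 42 kept their call and direction under the alternatives of the same test and 26 with an estimated correlation. Over all lists past the test, the number kept with an estimated correlation ran from 0 of 10 in the difference between changes and 0 of 6 in iTreg to 4 of 5 in Th1. With the filter at the 75th percentile too few myeloid and dendritic markers were left for a test. Counts of genes past the test stayed within 1.5 times under every alternative run, except that 8 tests of lineage genes passed within an array set, where fewer groups were tested.

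Values against naive cells that changed sign were, with quantile normalization, 0.22 for Il17a in Th1, 0.020 for Bcl6 in Th17, and in iTreg 0.15 for Gata3, 0.14 for Ifng, 0.52 for Il17a and 0.15 for Il10, and 0.082 for Il17a in nTreg. With one median they were 0.044 for Gata3 and 0.19 for Il17a in Th1, 0.14 for Bcl6 in Th17, in iTreg 0.69 for Gata3, 0.14 for Ifng, 0.48 for Il17a and 0.12 for Il10, and in nTreg 0.021 for Bcl6 and 0.053 for Il17a. With the mean of probe sets they were -0.16 for Il21 in Th2 and 0.18 for Bcl6 in Th17. With the deposited scaling they were 0.65 for Gata3 and 0.70 for Il17a in Th1, and 0.10 for Gata3 and 0.93 for Bcl6 in Th17. Tbx21 in iTreg against Th1 was at 0.27 with one median. In the difference between the nTreg and iTreg changes Gpr83 was at 0.16 with 4 times the pseudocount, and Nt5e and Izumo1r at 0.17 and 0.66 with the deposited scaling. The cause was not tested, except that the deposited scaling sets the array sets 2-fold apart by construction. Gata3 in iTreg passed with one median, and Gata3 in Th1, Bcl6 in Th17 and Izumo1r passed with the deposited scaling, as did Tbx21 in iTreg against Th1 at -1.03 without a sign change. Of all sign changes, 29 were of values past the test under neither setting.

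Leaving out 1 array gave ranges of -0.42 to 0.46 for Il21 in Th2, -0.11 to 0.023 for Bcl6 in Th17, -0.41 to 0.24 for Il17a in Th1, -0.043 to 0.62 for Il17a in Th2, -0.090 to 0.084 for Gata3 in iTreg, -0.13 to 0.041 for Il17a in iTreg and -0.11 to 0.010 for Tbx21 in iTreg against Th1, where a lone array is assumed to vary like the other groups. Replicate numbers did not pair the samples, with correlations of -0.0349 to 0.0235 over 15 pairs of groups, and with the replicate block 7757 genes passed for cultured against naive cells, 6959 for iTreg against nTreg and 6221 for the difference between changes. Low signal limits the calls: in the dimmest 3092 of the tested genes 15.6% to 34.5% passed over the 8 comparisons, with median SE of 0.33 to 0.54, against 51.4% to 80.2% in the brightest 3092, with 0.071 to 0.12.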

Other observations

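The replicate values of S100a8 and S100a9 were chosen after they were seen, and differences between replicates were not tested.

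Hspa1b, which encodes an inducible heat shock protein, had log2 levels of 13.92 to 14.94 in naive cells and nTreg and of 6.66 to 7.63 in the 4 cultured subsets. Malat1, a nuclear RNA, was at 6.52 and 6.43 in iTreg and at 9.83 to 12.75 on all other arrays.

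S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, differed between replicates of Th1, at 4.82 and 10.62 for S100a8 and 4.65 and 10.16 for S100a9. In Th2 the replicates were at 4.66 and 8.45 for S100a8 and at 5.72 and 7.76 for S100a9.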
